A study of Mus musculus with 7 samples.

How the data were processed

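Total RNA of arcuate nucleus tissue from 7 male C57BL/6J mice, 4 Dusp8-deficient and 3 control, was amplified, biotin-labelled and hybridised to an Illumina bead array, per the labels and the probe identifiers. The mice were switched to the high-fat diet at 8 to 10 weeks of age, and all were littermates, per the labels' protocols. The labels call the samples biological replicates and give no dissection day, litter or slide for any sample.

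The main values were intensities that the authors deposited without normalisation between arrays, per the file headers. From the values, these intensities are whole numbers that go below 0 and already had a background subtracted. The software and the background method are not given in the sources used here. A detection p-value per probe and array was deposited beside each intensity, per the file headers, and its method is not given in the sources used here. The columns of this table carry the genotype and a number of their own but no replicate number, so each array was used as 1 member of its group. A table of processed values deposited by the authors holds intensities on a linear scale, above 0 and rounded to whole numbers, with a median of 21 in each of its 7 columns. From the values they were quantile-normalised, and the constant that lifts them above 0 stays unknown. Each of its columns had a rank correlation of 0.9996 to 1 with 1 column of the main table, from the same labelled group. That table was used only as an alternative, and carries the replicate numbers of the labels.

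Intensities were corrected and normalised with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16, applies quantile normalisation and takes log2. A probe was tested when its detection p was below 0.05 in at least 3 of the 7 arrays, which kept 14067 of 25697 probes and left 11630 untested. Probes were named through the platform annotation, whose symbols were checked against a reference gene table by Entrez ID. In that annotation 23978 probes had 1 gene and none had several, 1719 were unnamed here, no symbol changed, and 16 IDs were not matched. Tested probes without a name stayed in the test. The tested probes covered 9720 genes. Where a gene had several probes, the one with the highest mean level stood for it in the gene lists, and probes that disagreed are given. A probe not above background in any array of a group has only a bound there. Its fold is the mean of the brighter group over the mean, per array, of the higher of the probe's own value and the lowest value among detected probes.

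Each probe was fitted with lmFit and eBayes, Dusp8-deficient minus control, two-sided, and p was adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. Log2 fold changes are given with the standard error from this fit (4 against 3 arrays). Exact permutation tests used all 35 splits of the 7 arrays. The number of arrays limits the precision.

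Before the data were examined, 31 gene lists were written for the tissue and the question, with 806 genes as named there, of which 551 were measured. They covered MAPK phosphatases, the Jnk pathway, the Erk and p38 pathways, immediate early genes, insulin and leptin signalling, arcuate peptides, arcuate receptors, the glucocorticoid response, the corticotropin axis, inflammation, interferon, the unfolded protein and heat shock responses, oxidative phosphorylation, ribosomal proteins, clock genes, the genes around Dusp8, and markers of cell types and neighbouring tissues. Dusp8 was left out of every list. Lists were tested with camera (preset correlation 0.01), adjusted over all lists, and again with an estimated correlation and with fry, under which 0 lists passed.

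The genes named were fixed by a rule written at the same time. They are Dusp8, the 10 genes per direction with the largest change among those past the threshold without overlap between the groups, filled up with the genes of smallest p named as not passing, 20 genes of the arcuate nucleus, the Jnk pathway, the glucocorticoid response and glia, and up to 4 members of smallest p of each list.

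The steps were tested on simulated data with the means and limma's moderated variances of these 14067 probes, in 20 runs with 200 changed probes each. Changes of 1.5-fold were recovered in 2.6% of cases, 2-fold in 33.9%, 4-fold in 97.9% and 5.7-fold in 99.7%, with 4.99% of the calls false. With a simulated 1.25-fold shift of all genes of 3 lists, with no correlation between genes, the myelin list was called in 19 of 20 runs and the insulin signalling and Jnk pathway lists in 20 of 20. The 23 lists that shared no gene with these gave 2 calls over all runs.

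The alternatives fixed beforehand changed the background correction, the normalisation, the filter, the variance model, the array weights, the threshold and the list test, used the processed values of the authors, added the replicate number as a block, or left out each array in turn. Added after seeing the data were a fit with the myelin list mean of each array as a covariate, a fit of replicates 1 to 3 of the processed values without the block, and camera with an estimated correlation with each array left out. Figures were drawn with matplotlib 3.10.9.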

Results

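Gene expression was measured in the arcuate nucleus, the part of the mediobasal hypothalamus that holds the Npy/Agrp and Pomc neurons that control feeding. The animals were male C57BL/6J mice of 40 weeks that had eaten a diet with 45% of its energy from fat for 30 weeks. Total RNA of 4 Dusp8-deficient mice and 3 littermate controls was hybridised to an Illumina bead array, 1 array per animal. Dusp8 encodes a dual-specificity phosphatase that removes phosphate from mitogen-activated protein kinases such as Jnk. The arrays are named here by the headings of the signal table, ko_108, ko_125, ko_148 and ko_168 for the Dusp8-deficient mice and wt_136, wt_145 and wt_177 for the controls. Of 25697 probes, between 12295 and 13976 were detected per array, and the mean signal per probe ranged from 58.0 to 74.9 units. Neither the number of detected probes (exact permutation p = 0.229, two-sided, 4 against 3 arrays) nor the mean signal (exact permutation p = 0.543) passed a test between the groups.

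The design asked what loss of Dusp8 changes in this tissue under a high-fat diet. Dusp8 itself was 5.72-fold lower in the Dusp8-deficient mice and was the only gene that passed the test. Its deposited signal was 77 to 104 units in the 4 Dusp8-deficient arrays and 540 to 624 units in the 3 control arrays, so that 16.2% of the control signal remained. Each of the 4 Dusp8-deficient arrays lay below each control. On the normalised log2 scale the means were 6.74 ± 0.34 (SD, n = 4) and 9.25 ± 0.04 (SD, n = 3). The log2 fold change was -2.52 with a standard error of 0.23 and a 95% interval from -3.02 to -2.01 (limma, adjusted p = 0.00963). The exact permutation p of this gene was 0.0286, the smallest that the 35 splits of 7 arrays allow. Dusp8 lies on chromosome 7 and is read by 1 probe, ILMN_1228031, which was detected on all arrays. Where this probe lies relative to the altered part of the gene is not given in the sources used here.

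**Figure D1:**
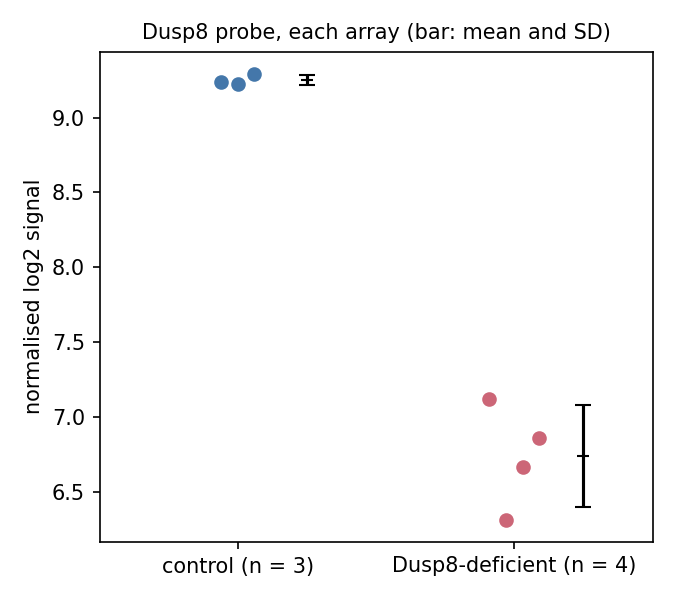
Normalised log2 signal of the Dusp8 probe in each array (points), with the mean and SD of each group (bars), for 3 control and 4 Dusp8-deficient mice. The Dusp8-deficient arrays have a mean of 6.74 and the control arrays a mean of 9.25, with no overlap.

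No other of the 14067 tested probes passed the threshold of 0.05 in limma after Benjamini-Hochberg adjustment, in either direction. An unadjusted p below 0.05 was reached by 677 probes (325 higher and 352 lower in the Dusp8-deficient arrays), or 4.81% of those tested, where 5% (703 probes) is the share under no change. The next smallest p after Dusp8 was 0.000271 for Glce, with an adjusted p of 0.996. The groups did not overlap for 783 probes, or 5.57%, against 5.71% by chance. The 95% interval of a probe reached a median of 0.57 log2 units to each side of its estimate, a factor of 1.48, and lay within a 2-fold change either way for 76.8% of the probes. With each probe's own variance in place of limma's moderated one, 0 probes passed and 567 had an unadjusted p below 0.05. The adjusted p of Dusp8 rose to 0.141 when dim probes were not filtered out, and to between 0.0560 and 0.111 when any 1 of ko_148, ko_168, wt_136, wt_145 or wt_177 was left out, while its log2 fold change stayed between -2.65 and -2.40 with any 1 array left out.

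**Figure D2:**
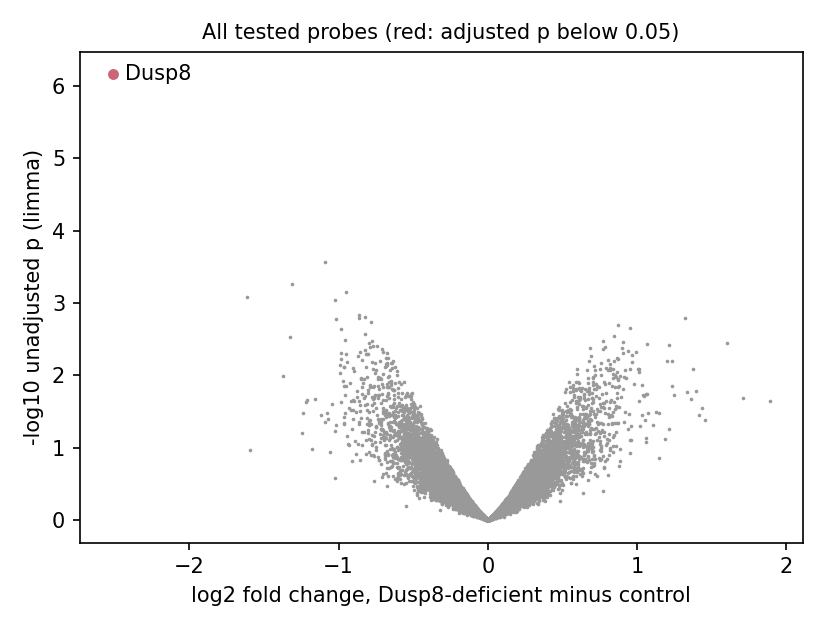
Log2 fold change (horizontal axis, Dusp8-deficient minus control) against -log10 of the unadjusted limma p (vertical axis) for the 14067 tested probes. Dusp8, at a log2 fold change of -2.52, is the only probe past an adjusted p of 0.05.

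No gene for the kinases that Dusp8 acts on, or for the pathways around them, passed the test at the mRNA level. Of 19 measured genes of the Jnk pathway, 12 were higher and 7 lower, and none passed (list adjusted p = 0.770, camera). The Jnk kinase genes themselves differed by -0.09 (SE 0.26) log2 units for Mapk8, -0.19 (SE 0.20) for Mapk9 and -0.01 (SE 0.40) for Mapk10, with 4 against 3 arrays, without passing. With 1 array left out, Mapk8 ran from -0.20 to 0.13 and Mapk10 from -0.25 to 0.34, and Mapk10 was 0.01 with an offset of 50 and 0.35 with replicates 1 to 3 of the processed values. A second Mapk9 probe read 0.49 (SE 0.30). Jun, a transcription factor that Jnk phosphorylates, was 0.76 (SE 0.36) log2 units higher, and Map3k1, an upstream kinase, read -0.79 (SE 0.35), without passing. Of 8 measured genes of the MAPK phosphatase list, which leaves out Dusp8, 5 were higher and 3 lower (adjusted p = 0.542). Among them were Styx at 0.43, Dusp6 at 0.45, Dusp1 at 0.41 and Dusp7 at -0.36 log2 units. Of 2 dimmer Dusp6 probes, 1 read 0.06 and 1 read -0.04. The 16 measured genes of the Erk and p38 pathways split into 5 higher and 11 lower (adjusted p = 0.934), with Map2k6 at -0.35 log2 units and Map2k3 at least 1.29-fold higher on a probe not above background in any control, without passing. Of 14 immediate early genes, markers of recent neuronal activity, 9 were higher and 5 lower (adjusted p = 0.542), with Fos at 0.10 (SE 0.23), and from -0.08 to 0.19 with 1 array left out. The Fos probe was detected in 2 of 3 controls. Without passing, Npas4 was at least 1.22-fold lower on a probe not above background in any Dusp8-deficient array, and Arc at least 1.39-fold higher on a probe not above background in any control.

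Insulin and leptin signalling genes did not pass either. Of 26 measured insulin signalling genes, 16 were lower and 10 higher, with a mean log2 difference of -0.10 (adjusted p = 0.542). Gsk3b, a kinase that insulin signalling inhibits, read -0.48 (SE 0.20), Mtor -0.53 (SE 0.25), Ptpn1 -0.40 (SE 0.25) and the insulin receptor gene Insr 0.42 (SE 0.29). A dimmer Mtor probe read 0.42. Of 14 leptin signalling genes, 8 were higher and 6 lower (adjusted p = 0.952). Cish read 0.60 (SE 0.34), Stat5a -0.36 (SE 0.35), and the leptin receptor gene Lepr 0.06 (SE 0.18). The Lepr probe was detected in 1 of 3 controls. Its signal of 5 to 9 units lies near the background, which limits what can be seen.

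Genes for the peptides of arcuate neurons had wide intervals and did not pass. Npy, an appetite-stimulating peptide, was 2.27-fold lower on average (log2 fold change -1.18, 95% interval -2.65 to 0.29), Ghrh, the growth hormone-releasing hormone, read -1.02 (SE 0.86), Pomc, the precursor of the melanocortins, -0.64 (SE 0.41), Cartpt -0.53 (SE 0.46) and Th, which marks dopamine neurons, -0.57 (SE 0.35). Sst read -0.19 (SE 0.21). Kiss1 read 0.13 (SE 0.24) on a probe detected in 2 of 4 Dusp8-deficient arrays and 1 of 3 controls. No probe of the annotation used here is named Agrp. Of the 21 measured arcuate peptide and transmitter genes, 10 were higher and 11 lower, and none passed (adjusted p = 0.661). Array ko_108 held the lowest values of Npy, Ghrh, Cartpt and Th, with Npy at 6.08 against 8.55 to 9.83 elsewhere, Ghrh at 4.51 against 8.10 to 8.78 and Th at 4.45 against 5.37 to 6.13. Without that array the log2 fold changes were -0.48 for Npy, -0.05 for Ghrh and -0.02 for Cartpt, and the mean difference of the list went from -0.18 to -0.02. Pomc was at 6.44 in the control wt_177 and at 4.46 to 5.24 in all other arrays. Its probe was detected in 3 of 4 Dusp8-deficient arrays and 2 of 3 controls. Among 21 arcuate receptors and regulators, 9 were higher and 12 lower (adjusted p = 0.428). Npy1r, an Npy receptor, read -0.70 (SE 0.19) and Nr0b1 -0.82 (SE 0.23), both at an adjusted p of 0.0533 (limma, adjusted over the list alone), and Esr1, the estrogen receptor, read -0.76 (SE 0.28). No gene of any of the 31 lists passed when adjusted over the list alone, and none passed over all probes tested.

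Oligodendrocyte and myelin genes formed the only one of the 31 lists that passed. Of 17 measured members, 16 were higher in the Dusp8-deficient arrays, by 0.37 log2 units on average (camera with a preset correlation, adjusted p = 0.00647), although no single member passed. With the correlation between its genes estimated, at 0.62 against the preset 0.01, the adjusted p was 0.828 (camera). The test fry, which asks whether the genes of a list move one way, gave an adjusted p of 0.926. Gjc3 read 0.69 (SE 0.33), the myelin gene Mobp 0.89 (SE 0.49), Trf 0.84 (SE 0.48) and Tspan2 0.59 (SE 0.35). All 17 members were at their highest in array ko_108, whose list mean lay 1.04 log2 units above the mean of the arrays, while the other arrays lay between -0.47 and 0.02. Without ko_108 the mean difference was 0.08 (adjusted p = 0.853), and without wt_145 it was 0.24 (adjusted p = 0.271). The list mean per array gave an exact permutation p of 0.371, and with array quality weights the list had an adjusted p of 0.135.

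**Figure D3:**
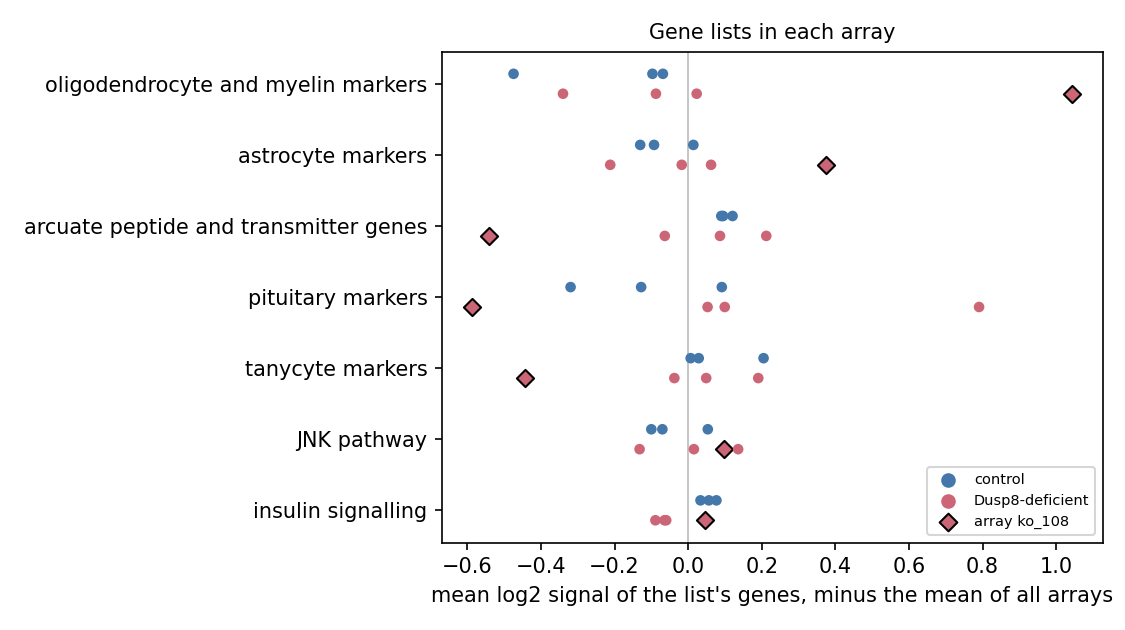
Mean log2 signal of the genes of 7 lists in each array, minus the mean of all arrays (horizontal axis), for 3 control arrays (blue) and 4 Dusp8-deficient arrays (red, with ko_108 as a diamond). Array ko_108 lies at 1.04 for myelin markers and at -0.54 for arcuate peptide and transmitter genes.

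The markers of other cell types did not pass. Of 14 astrocyte markers, 11 were higher (adjusted p = 0.428), with Ppp1r3c at 0.52, Slc1a2 at 0.59, Fgfr3 at -0.61 and Gfap at 0.40 (SE 0.27). Array ko_108 was again the highest in this list, at 0.38, and the mean difference without it was -0.01. Of 14 meningeal and fibroblast markers, 11 were higher (adjusted p = 0.269), among them Col1a2 at 0.47, Ogn at 0.50 and Igfbp2 at 0.94, and other Ogn probes read 0.61 and -0.14. That list passed when ko_108 was left out (adjusted p = 0.0270) or wt_136 (adjusted p = 0.00467), but with an estimated correlation the adjusted p = 0.957 and 0.706 in these fits. Over all arrays its adjusted p was 0.828 with an estimated correlation and 0.926 with fry, and its exact permutation p was 0.429. Microglia and macrophage markers split into 9 higher and 8 lower (adjusted p = 0.923), with Aif1 at 0.23 (SE 0.20), Cx3cr1 at -0.41 and Trem2 at 0.40, and dimmer Aif1 probes read -0.16 and -0.05. Neuron markers split into 10 higher and 10 lower (adjusted p = 0.900), with Celf4 at 0.58 and Elavl4 at -0.49. Of 13 markers of tanycytes, the glia that line the third ventricle, 8 were lower (adjusted p = 0.552), with Vcan at -0.58 and Crym at -0.55. Array ko_108 was the lowest in this list, at -0.44, and the mean difference went from -0.14 to -0.01 without it. Oligodendrocyte precursor markers (6 of 10 higher, adjusted p = 0.952), ependymal markers (5 of 11, adjusted p = 0.770), vascular markers (7 of 16, adjusted p = 0.900) and red blood cell markers (2 of 3, adjusted p = 0.661) gave no call. Nor did markers of the choroid plexus (5 of 6 higher, adjusted p = 0.428), the pituitary (5 of 7, adjusted p = 0.788) and neighbouring brain regions (8 of 12, adjusted p = 0.788, with Oxt at -0.55). Tshb, a pituitary marker, was at least 2.49-fold higher on average on a probe not above background in any control, without passing. Its log2 signal was 5.68 to 7.24 in ko_125, ko_148 and ko_168, but 4.17 in ko_108, below the 4.35 to 4.55 of the controls.

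Stress, hormone and immune responses were likewise uncalled. Of 21 genes of the glucocorticoid response, 10 were higher and 11 lower (adjusted p = 0.767), and the mean difference of 0.07 was 0.01 without ko_108. Fkbp5 read 0.39 (SE 0.45), Nr3c1, the glucocorticoid receptor, 0.05 (SE 0.29, and from -0.21 to 0.20 with 1 array left out), and Tsc22d3 0.38 (SE 0.25) on its brighter probe and -0.40 (SE 0.38) on the other. The log2 signal of Fkbp5 ran from 4.66 to 6.46 in the Dusp8-deficient arrays and from 4.46 to 6.02 in the controls. Of 9 genes of the corticotropin axis and steroid receptors, 6 were lower (adjusted p = 0.441), with Hsd11b1 at -0.44. Of 21 interferon response genes, 11 were lower (adjusted p = 0.767), with Oasl2 at -0.93 and Bst2 at -0.38, and array ko_108 was the lowest in this list, at -0.48, with a mean difference of -0.07 that became 0.09 without it. The inflammatory mediators (6 of 12 higher, adjusted p = 0.864, with Nfkbiz at -0.51), the unfolded protein response (13 of 22, adjusted p = 0.788, with Hsp90b1 at 0.49) and the heat shock response (8 of 17, adjusted p = 0.923, with Dnaja1 at -0.53) did not pass. Oxidative phosphorylation genes were higher in 42 of 67 cases, by 0.08 log2 units on average (adjusted p = 0.428), with Ndufa1 at 0.58 and Ndufab1 at -0.48. Array ko_108 was the highest in this list, and without it the mean difference was 0.04. Cytosolic ribosomal protein genes (18 of 44 higher, adjusted p = 0.934, with Rps13 at 0.56) and clock genes (10 of 17, adjusted p = 0.770, with Rora at 0.29) did not pass. The median, mean and camera direction differed in sign for 6 of these lists, namely the glucocorticoid response, the heat shock response, the inflammatory mediators, the Erk and p38 pathways, the vascular markers and the neighbouring brain regions. With 1 array left out, the mean difference of 17 of the 31 lists changed sign in at least 1 fit.

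Genes that lie near Dusp8 on distal chromosome 7 were lower in 28 of 40 measured cases, with a mean log2 difference of -0.13. The list did not pass after adjustment over all lists (camera, adjusted p = 0.269), and its mean per array had an exact permutation p of 0.0571. The members of smallest p were Sct, which encodes secretin, at -0.78 (SE 0.29), Bet1l at -0.53, Slc25a22, a mitochondrial glutamate carrier, at -0.49 and Fadd at -0.49. Dimmer Fadd probes read 0.50 and -0.20, and a further one was not above background in any control. No member passed over the list alone.

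Beyond Dusp8, the genes of smallest p in each direction are named as not passing, all at an adjusted p of 0.996. Lower in the Dusp8-deficient arrays were Glce (log2 fold change -1.09, SE 0.20), an enzyme of heparan sulfate synthesis, Nek6 (-1.61, SE 0.34), a mitotic kinase, Sesn1 (-1.02, SE 0.22), a stress-responsive inhibitor of mTORC1, Rgp1 (-0.95), Asb7 (-0.87) and Gpr75 (-0.86). Dmrtc1a read -1.31 on a probe detected in 1 of 4 Dusp8-deficient arrays and -0.40 on a second probe. Cnnm3 read -1.02 on 1 probe and 0.29 on the other. Atp11a was at least 1.52-fold lower on a probe not above background in any Dusp8-deficient array, and its other probe read 0.51. Higher were Ccdc151 (1.60, SE 0.42), Evi2a (1.21, SE 0.32), Clk3 (1.06), Thtpa (0.90), Taf11 (0.87) and Pex26 (0.84). Ggct, of the glutathione cycle, read 1.32 on its brightest probe and -0.04 and 0.43 on others, and a further probe was not above background in any control. Egfl7 read 0.90 on 1 probe and -0.27 and -0.36 on the others. Pdlim5 was at least 1.75-fold and Pex5l at least 1.49-fold higher on probes not above background in any control, and the other Pdlim5 probes read 0.01 and 0.10.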

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

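Of the tests of explanations in this part, only the count of splits was chosen before its result was seen. A value was singled out where 1 of the 4 Dusp8-deficient arrays lay far from the other 3, by Dixon's criterion. Chance singles out about 1 in 20 groups, or 9.3 of the 186 examined, and 11 were found. The 3 control arrays were too few to examine.

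Of these 11, 6 lay in array ko_108. Its mean signal was 58.0 units against 73.4 to 74.9 in the other Dusp8-deficient arrays. Its log2 signal was 8.68 for Cartpt against 10.5 to 10.8, 4.51 for Ghrh against 8.10 to 8.69, 7.28 for Atp5e against 7.98 to 8.06, 7.54 for Tspan2 against 6.77 to 6.85 and 7.08 for Evi2a against 5.76 to 5.93. In ko_125, Tnr was at 5.27 against 4.27 to 4.33, Tbx19 at 6.02 against 4.22 to 4.33 and Chgb at 7.72 against 6.79 to 6.88. In ko_168, Tekt1 was at 5.99 against 4.97 to 5.10. In ko_148, the mean score of leptin signalling was 0.10 against -0.03 to -0.02. Set against the controls, Tnr and Tbx19 in ko_125 lay within their ranges of 4.26 to 5.68 and 4.39 to 6.06. The mean signal and Atp5e in ko_108 lay slightly below the lowest controls, at 60.6 units and 7.29. The other flagged values lay outside the range of the controls.

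The call of the myelin list, 0.37 log2 units higher in the Dusp8-deficient arrays, goes together with array ko_108, and chance cannot be excluded for it, since 26 of the 35 splits called at least 1 list, as the real split did, and the highest count among the others was 4. The tables argue against the normalisation between arrays, since the lower of the mean differences with cyclic loess and median scaling, in place of quantile normalisation, was 0.375. A larger share of white matter in the sample of ko_108 is a possible explanation that stays open, since the difference of 0.079 without ko_108 and the levels there of Mag, at 10.9 against 9.36 to 10.1, and Mbp, at 10.7 against 8.74 to 9.39, are the pattern itself and do not test it. Neuron markers, which more white matter would be expected to lower, had their highest mean score in ko_108, at 0.149 against -0.12 to 0.11 in the 6 other arrays, above the next by less than the SD of those arrays (0.08), so this value does not decide. Of the list's 17 measured genes, 16 were detected in all 3 controls and 2 also stand in another list, and whether the animals without ko_108 share a rise through loss of Dusp8 also remains open, with a mean difference of 0.079 over the 6 other arrays and a 95% interval from -0.39 to 0.55.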

How the results depend on the processing

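The tests chosen after seeing the data are the fits with the myelin list mean as a covariate, with replicates 1 to 3 without a block, and camera with an estimated correlation with 1 array left out, which called 0 lists in all 7 fits. The log2 fold change of Dusp8 stayed between -2.68 and -2.13 over 13 settings, 10 of which kept its call, with adjusted p from 0.000449 to 0.273, and it fell between -2.65 and -2.40 with 1 array left out, where 2 of 7 fits kept the call. Its call ended without the filter on dim probes (log2 fold change -2.52, adjusted p 0.141, 0 probes changed). That fit used the same normalised values, and 25697 probes in place of 14067 entered the adjustment and the moderated variance. The unadjusted p of Dusp8 in the main fit, 6.8e-07 (limma), would pass the threshold among 25697 probes too. The larger number of probes alone therefore did not end the call. Scaled to 14067 probes, the adjusted p of 0.141 would still miss the threshold. The changed moderated variance was therefore enough to end the call, though no fit changed it alone. The call also ended with replicates 1 to 3 of the authors' processed values (-2.60, adjusted p 0.0899, 0 probes), where fewer samples entered. The values showed no sign that the replicate numbers pair the samples, though they cannot exclude it. Same-numbered deviations correlated at -0.07, 0.07 and -0.00067, and not every sample correlated best with its own number. With the replicate block Dusp8 read -2.60 (adjusted p 0.273, 0 probes changed), with 1 list called. With each probe's own variance in place of a moderated one, 0 probes passed, so Dusp8 lost its call there too. That setting is not among the 13 counted above. With 1 array left out, 0 to 1 probes and 0 to 2 gene lists were called. The lists called numbered 0 with array quality weights, with the myelin covariate, with an estimated correlation and with fry. The estimated correlation of the myelin list was 0.62, against the preset 0.01, and the myelin covariate is that list's own mean per array. For array quality weights and fry the cause was not tested. Slide as a block was not run, since no slide is given in the sources used here, and the myelin covariate gives no value for the myelin list itself.

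Of 148 other named genes, none passed in any fit that tested them. The strict filter, detection p below 0.01 in all arrays, left 72 of them untested, and the fits with 1 array left out 3 to 6 each. In the fits that tested them, 141 kept their sign with 7 arrays or with replicates 1 to 3, as did 140 with 1 array left out. Of 31 lists, 17 and 14 kept the sign of their mean, the pituitary and red blood cell lists having no value under the strict filter. The reversed values follow as log2 differences, and none passed. The mean of ribosomal protein genes was 0.021 without further background correction and 0.021 in the authors' processed values. With normexp at an offset of 50, Mapk10 was 0.014, ribosomal proteins 0.0033 and neighbouring brain regions 0.00088, and with neqc at that offset Mapk10 was 0.011 and neighbouring brain regions 0.00012. Calml4 was -0.0055 with median scaling. Without the filter, inflammatory mediators were 0.011 and neighbouring brain regions 0.068. With the strict filter, Erk and p38 pathways were -0.031, leptin signalling -0.0022 and oligodendrocyte precursors -0.014. With array quality weights, Hba-a1 was 0.045, ribosomal proteins 0.0024, oligodendrocyte precursors -0.054, ependymal markers 0.026 and vascular markers -0.0054. With replicates 1 to 3, and equally with the replicate block, Mapk10 was 0.35, Fos -0.082, Hbb-b2 -0.057, ribosomal proteins 0.0045, clock genes -0.0049 and neighbouring brain regions 0.076. With the myelin covariate, Cartpt was 0.034, Ghrh 0.045, Calml4 -0.10, the glucocorticoid response -0.036, inflammatory mediators 0.011, interferon response 0.10, heat shock response -0.0095, ribosomal proteins 0.036, neurons -0.034, oligodendrocyte precursors -0.021, tanycytes 0.0061 and vascular markers -0.050. With all probes of a gene averaged, Erk and p38 pathways were -0.0036. The cause of these changes was not tested.

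With 1 array left out, the genes that reversed ranged from -0.064 to 0.18 for Calml4, -0.20 to 0.13 for Mapk8, -0.25 to 0.34 for Mapk10, -0.046 to 0.30 for Chgb, -0.48 to 0.38 for Hba-a1, -0.21 to 0.20 for Nr3c1, -0.075 to 0.19 for Fos and -0.0041 to 1.04 for Ttr. The lists ranged from -0.078 to 0.0084 for inflammatory mediators, -0.15 to 0.086 for interferon, -0.0037 to 0.077 for heat shock, -0.031 to 0.025 for ribosomal proteins, -0.028 to 0.094 for neurons, -0.011 to 0.21 for astrocytes, -0.032 to 0.093 for vascular markers and -0.037 to 0.072 for the Erk and p38 pathways. They ranged from -0.16 to 0.061 for ependymal markers, -0.11 to 0.43 for pituitary, -0.026 to 0.047 for leptin, -0.024 to 0.080 for the unfolded protein response, -0.0077 to 0.063 for clock genes, -0.15 to 0.060 for neighbouring brain regions, -0.016 to 0.10 for microglia, -0.078 to 0.19 for oligodendrocyte precursors and -0.0075 to 0.46 for red blood cells. The 11630 probes below the filter lie near the background, where signal limits what can be seen, and the fit without the filter, which included them, called 0 probes, with 1204 at an unadjusted p below 0.05.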

Other observations

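All tests in this part except the count of splits for the probes were chosen after the results they measure, or values close to them, had been seen. Several gene lists, among them markers of cell types and neighbouring tissues, varied widely between animals of the same group. Myelin markers had a within-group SD of 0.49 log2 units, where random lists of the same size and level had a median of 0.09, and none of 2000 such lists varied as much. Red blood cell markers had an SD of 0.47, which 5 of 2000 random lists reached. The SD was 0.39 without ko_125 (90 of 2000) and 0.41 without wt_177 (61 of 2000). Pituitary markers had an SD of 0.45, meningeal and fibroblast markers 0.30, arcuate peptide and transmitter genes 0.26 and interferon response genes 0.25, and again none of 2000 random lists varied as much as any of these 4. The corticotropin axis and steroid receptor list had an SD of 0.33, which 2 of 2000 random lists reached. The vasopressin gene Avp, with an SD of 2.04 by itself, is 1 of the 9 measured genes of that list. Its spread can therefore rest largely on 1 gene, and the list without Avp was not tested. For some of these lists array ko_108 carried much of the spread. Without it the SD was 0.21 for myelin markers (3 of 2000 random lists varied as much), 0.10 for arcuate peptide and transmitter genes (285 of 2000) and 0.09 for interferon response genes (633 of 2000). Other lists kept their spread without that array. The SD was then 0.24 for meningeal and fibroblast markers (0 of 2000), 0.33 for pituitary markers (0 of 2000), 0.52 for red blood cell markers (2 of 2000) and 0.35 for the corticotropin list (1 of 2000). Insulin signalling (SD 0.05, and 0.02 without ko_108) and leptin signalling (SD 0.07) varied no more than most random lists, of which 85.4% and 83.8% varied as much.

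The single gene with the largest spread within groups was Avp, the gene of vasopressin, which is made among others in the supraoptic and paraventricular nuclei. Its log2 signal ran from 5.96 in ko_168 to 11.2 in ko_148 and from 7.23 to 10.4 in the controls, an SD of 2.04 against a median of 0.34 over all genes. Without ko_168 its SD was 1.60, and Bpifb1 had the largest, at 1.74. Trh, made in the paraventricular nucleus, was at 7.81 in ko_108 and at most 6.31 in the other arrays. Cga, the common subunit of the glycoprotein hormones, was at 4.22 in ko_108 and at 7.64 in ko_125. In ko_108 the mean score of tanycyte markers was -0.44, of meningeal and fibroblast markers -0.33, of pituitary markers -0.59 and of neighbouring brain region markers 0.27. These genes were chosen after their values were seen.

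The real split called 1 probe, Dusp8, and the highest count among the other splits was 0, a share of 1 of 35 splits, the smallest they allow. Dusp8 is the targeted gene, and each other split puts Dusp8-deficient and control arrays in the same group. The count therefore cannot test chance for anything beyond the loss of Dusp8 itself. Whether many small changes lie below the threshold stays open. The 677 probes of the real split with an unadjusted p below 0.05 lay within the 441 to 1107 of the other splits, 21 of the 35 splits had at least as many, and 2.6% of simulated 1.5-fold changes were recovered. Single changes of 2-fold or less may still have been missed, since 33.9% of simulated 2-fold changes were recovered at these group sizes, against 97.9% of 4-fold ones. Those runs held 200 changed probes each, which eases the adjusted threshold, and drew their noise from limma's moderated variances. Recovery of a lone change, for which the adjusted threshold is stricter, was not simulated.

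The lower mean of the genes near Dusp8 could come from an inherited chromosome segment around the targeted gene, a hypothesis that applies where a targeted allele was made in cells of another strain. The 40 measured genes nearest to Dusp8 along chromosome 7 had a mean log2 difference of -0.08, and 3.35% of 8891 equally long runs of genes elsewhere had a mean as low. These runs overlap and are not independent, and only the low side, the direction already seen, was counted. Of these 40 genes, 34 also stand in the list fixed beforehand, so the test is not independent of it. Chance among the lists tested stays open as well, with an adjusted p of 0.269, and an effect of Dusp8 loss on these genes was not tested. Gene order was taken from a reference gene table.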
